A study of Homo sapiens with 60 samples.

How the data were processed

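The series held 60 sequencing libraries related to the human hepatoblastoma-derived cell line HepG2. Of these, 46 were Pseudo-seq libraries, which map pseudouridine from reverse transcription stops at bases labelled with the carbodiimide CMC. They comprised 11 pairs of CMC-treated and untreated libraries of chromatin-associated RNA, and 24 libraries of an in vitro transcribed oligo pool treated with a recombinant pseudouridine synthase, with an extract labelled HepG2 NE, or with no enzyme. The CMC concentration was 0.4 M. The remaining 14 were poly(A)+ mRNA libraries: 2 PUS1 knockout and 2 wild-type, 3 PUS7 knockdown and 3 control, and 2 RPUSD4 knockdown and 2 control libraries. Groups were taken from the sample titles. In the PUS1 in vitro pair a characteristic named another enzyme, and in the RPUSD4 libraries the genotype field named PUS7, so the titles and source names were used there.

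The submitters' processing notes named cutadapt, Bowtie, TopHat2, STAR and DESeq2 and the genome build GRCh37, with no versions and no roles. The deposited chromatin values were a score, the Pseudo-seq peak value of each of the 11 library pairs at each listed position, and could be negative. The deposited in vitro tables held a peak value score per library pair and a Z-score of the CMC-treated library with and without enzyme, with a reference distribution that was not stated. The deposited expression table held a log2 fold change, its standard error, the Wald statistic and a p value and adjusted p value per gene, made by the authors with DESeq2, and no values per library. The deposited splicing tables had the layout of rMATS output and held junction counts per library, inclusion levels between 0 and 1, a p value and an FDR per event. The files used give no read depth per library for Pseudo-seq or for the expression table, so no counting interval was given for those values.

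The comparison behind the 5 splicing tables that name no enzyme was taken as PUS1 knockout against wild type by elimination. Across genes, the ratio of their junction reads (second over first group) correlated with the coded fold change of the PUS1 expression table with Pearson's r of 0.489 (mutually exclusive exons) to 0.632 (retained introns), against 0.0112 in the PUS7 table and 0.0635 in the RPUSD4 table; genes are not independent replicates. Neither the splicing tables nor the expression table named which group was depleted of the enzyme. Differences are therefore given as first minus second group, and fold changes as coded; a positive coded fold change corresponded to more junction reads in the second group.

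The comma-separated junction counts of the PUS7 and RPUSD4 tables had been partly merged by a spreadsheet. They were split again by requiring whole numbers that gave back the deposited inclusion levels within 0.00051 and library depths within 4-fold of each other. This restored 2450 of 23392 PUS7 events and 4247 of 20841 RPUSD4 events, and left out 29 and 56 events. The Benjamini-Hochberg FDR recomputed from the deposited p values matched the deposited FDR of the 5 PUS1 tables and, within its rounding, that of PUS7, where the recomputed value was used. The RPUSD4 table's deposited FDR was kept, since recomputing over the listed events did not give it back (639 events under 0.05 against 809 deposited). Of the 809, 0 had an absolute inclusion difference under 0.095, so significant events with small differences were missing from it. The junction reads summed over the listed skipped exons ranged from 8373957 to 11964220 per library for PUS1, 8819004 to 13398789 for PUS7 and 14693237 to 24079303 for RPUSD4.

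Splicing events with at least 10 junction reads in every library were tested. Events were called at an rMATS FDR under 0.05 with an absolute inclusion difference of at least 0.1. As a test with spread estimated between libraries, limma 3.58.1 in R 4.3.3 was fitted to the log2 odds of inclusion of skipped exons, with 0.5 added to each count and weights from the binomial precision, with the same difference and a Benjamini-Hochberg adjusted p under 0.05. A test on reads pooled within groups, a z-test of the log odds that takes no account of the spread between libraries, was run on every split. limma was tested on simulated data with 100 changed exons of each size and an SD of 0.2 of the natural log odds. Every simulated exon had this same SD, and the changed exons were drawn from those of intermediate inclusion. Whether libraries at the same position of both groups were paired was checked from the correlation of their deviations from their group mean, which was 0.0500 for PUS1, 0.147, 0.135 and 0.0529 for PUS7 and 0.0247 for RPUSD4. No block was used, since not every value passed 0.1 and the tables do not print replicate numbers.

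Gene lists fixed before the data were examined (22 in all) were tested on the deposited Wald statistic with limma's cameraPR at a preset correlation of 0.01. An estimated correlation could not be had, since it needs values per library. Of 100 random lists, 2 had p under 0.05. Genes drawn at random need not vary together as genes of a real list may, so this does not test the preset correlation. Gene symbols came from the Ensembl identifiers, of which 55665 of 63677 matched a name. Shares were given with exact Clopper-Pearson 95% intervals. Sites were placed in features, and flanking bases read, with GENCODE release 44 mapped to GRCh37 and the GRCh37 sequence, using pysam 0.24.0 and samtools 1.23.1; pandas 2.3.3 and scipy 1.17.1 did the rest, and all Fisher's exact tests were two-sided. Coordinates are 1-based on GRCh37.

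Named items followed a rule written before the data were examined: PUS1, the 10 highest and 10 lowest coded fold changes among called genes with a mean of at least 100 normalized counts, up to 4 members of each list, the 10 skipped exons with the largest difference per comparison among calls whose libraries did not overlap and 3 of each other event type, the 10 highest chromatin sites, the 3 highest in vitro sites per enzyme, up to 10 called events per comparison with a chromatin site inside, by difference, and called events of the synthase genes. A few items that the rule selects are not reported here. The alternatives tried were stricter thresholds, other read and fold change minimums, another added count, no weights, leaving out each library, a block by position, a rank-based list test, and restricted site and event sets. The labels do not say whether replicates came from separate cultures, so p values measure only the spread between these samples.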

Results

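The data comprised 22 chromatin Pseudo-seq libraries, 24 in vitro Pseudo-seq libraries and 14 mRNA libraries. They address which human pre-mRNA positions carry pseudouridine, which synthases can make them, and how expression and splicing differed when PUS1, PUS7 or RPUSD4 was depleted in HepG2 cells.

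The chromatin RNA list held 4860 uridines in 1018 genes. Most lay in pre-mRNA: 1900 sites (39.1%, 95% interval 37.7 to 40.5) were intronic, 1229 (25.3%) were in coding exons, 718 (14.8%) in untranslated exons and 880 (18.1%) in non-coding exons. A further 81 lay in the ribosomal RNA precursor and 47 in mitochondrial RNA. The oncofetal surface protein gene GPC3 had 428 sites, 425 of them intronic. It was followed by FNDC3B (136 sites), the fibronectin gene FN1 (115), the protease inhibitor gene A2M (90), the antisense RNA KCNQ1OT1 (73), the apolipoprotein gene APOB (71) and the splicing factor gene RBM39 (64). Of the intronic sites, 97 (5.11%) lay within 50 nt upstream of a 3' splice site and 41 within 50 nt downstream of a 5' splice site. Within 500 nt of an exon there were 566 (29.8%). How much intron sequence lies this near was not counted, so these shares show neither enrichment nor avoidance.

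The highest peak values were in small nuclear and small nucleolar RNAs. The minor spliceosome RNA RNU6ATAC had a median peak value of 30.5 over 11 library pairs (mean 28.9 ± 2.42 SD) at position 137029604 of chromosome 9. Its pseudogenes RNU6ATAC2P (30.3) and RNU6ATAC26P (26.3) were listed as well and share sequence with it. The H/ACA guide RNAs SNORA69, within RPL39 (28.6), SNORA75, within the nucleolin gene NCL (27.5), SNORA28, within EIF5 (27.0), SNORA13 (26.5), SNORA12 (26.4) and SNORA7B (24.2) followed. An intronic position was among the highest, in RALGAPA1 on chromosome 14 at 36232122, with a median of 29.2. Peaks in 10 or 11 pairs were found at 170 sites. Of these, 94 (55.3%, 95% interval 47.5 to 62.9) were in non-coding exons and 22 (12.9%) in introns.

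Most listed sites rested on fewer pairs. A peak value of at least 1 was reached in 7 of 11 pairs at 3608 sites, in 8 at 880, in 9 at 202, in 10 at 73 and in 11 at 97. A binomial distribution cut at 7 would give 40.5 sites at 10 pairs and 2.62 at 11. Across the sites, the median Spearman correlation between library pairs was 0.00589 (range -0.0723 to 0.0705), and sites are not independent replicates. All listed sites passed in at least 7 of these same pairs, and such a selection can itself lower the correlation. The value therefore does not measure how well the libraries agree. An adenine followed 77.3% of the sites placed in the genome (95% interval 76.0 to 78.4), against 20.1% of other uridines within 50 nt. That share was 80.2% at sites in 7 pairs and 26.0% at sites in 10 or 11 (Fisher's exact p = 8.6e-43), and was 24.1% at 195 sites in small nuclear and nucleolar RNA genes.

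**Figure D1:**
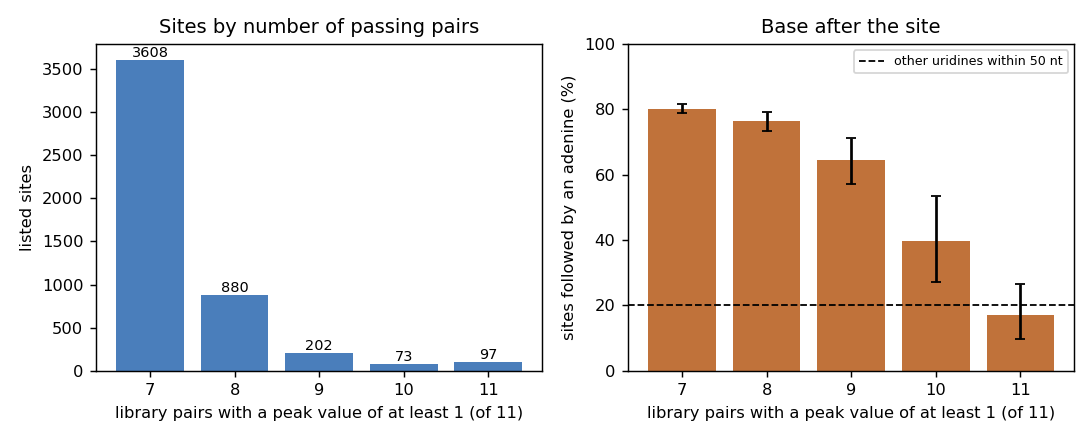
Left, listed sites (bars) by the number of library pairs, of 11, with a peak value of at least 1. Right, percent of sites followed by an adenine, with exact 95% intervals, which was 80.2% at 7 pairs and 17.0% at 11; the dashed line is other uridines within 50 nt (20.1%).

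The in vitro pool asked which synthases can modify listed sites. PUS1 was assigned 226 sites, PUS7 139, RPUSD4 24, RPUSD2 20, TRUB1 17, TRUB2 12, PUS10 5 and PUS7L 2, and the HepG2 extract 143. The highest Z-scores with PUS7 were in the TGF-beta receptor gene TGFBR2 (74.2), AFMID (70.4) and the cyclin gene CCNT2 (64.1). With PUS1 they were in the desaturase gene SCD (65.9), LINC01146 (58.6) and SEC23A (57.6), and with TRUB1 in COBLL1 (86.1), SMLR1 (75.6) and the mitochondrial chaperone gene HSPD1 (74.8). SMLR1 and HSPD1 were also peaks in all 11 chromatin pairs. The highest RPUSD2 sites were in the guide RNA SCARNA5 (47.2), in TAF1D at the SNORA8 locus (44.8) and in SNHG14 (35.7). RPUSD4 was highest at GMDS (52.3), A1CF (22.4) and FN1 (19.3), TRUB2 at GPAM (24.95), LRPPRC (17.2) and PEG3 (15.9), and PUS10 at COBLL1 (14.5), A2M (12.1) and SELENOP (9.93). PUS7L was assigned sites in FDFT1 (5.88) and SNX5 (5.21), and the extract was highest at IL17RB (48.5), UTRN (47.5) and ZNF217 (41.1).

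The no-enzyme Z-score differed between the site lists of the enzymes. The median no-enzyme Z-score was 0.867 at PUS1 sites, 0.630 at PUS7 sites and 0.761 at TRUB1 sites, but 9.58 at RPUSD4 sites, 8.29 at TRUB2 sites and 4.93 at RPUSD2 sites. All 24 RPUSD4 sites had a no-enzyme Z-score of at least 5. It was at most 3.999 at PUS1 and PUS7 sites, and 5.23 to 11.4 at RPUSD4 sites. The lowest Z-score with enzyme was 5.08 for PUS1, 5.06 for PUS7, 12.5 for RPUSD4 and 12.9 for TRUB2. Sites may thus have been listed by unlike rules, which are not stated. The numbers of sites and their no-enzyme values therefore do not compare the enzymes. The no-enzyme value was the same at all 15 positions shared by PUS1 and PUS7 and all 9 shared by PUS1 and the extract. It was also the same at all 6 shared by PUS7 and the extract, all 4 shared by TRUB2 and RPUSD4 and the 1 shared by PUS1 and TRUB1. In other pairs it differed between entries. At 8 positions listed for RPUSD4 and for the extract, the median was 9.62 in the RPUSD4 entries and 0.723 in the extract entries. At these positions the high values went with the no-enzyme reference, not with the site. PUS1 and PUS7 shared 15 of the 541 assigned positions, and TRUB2 and RPUSD4 shared 4. No test of sharing is given, since every position in this list has an assignment and which positions without one the pool held is not known. There was 1 library pair per enzyme, so no spread between replicates could be given, and depths are unknown.

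**Figure D2:**
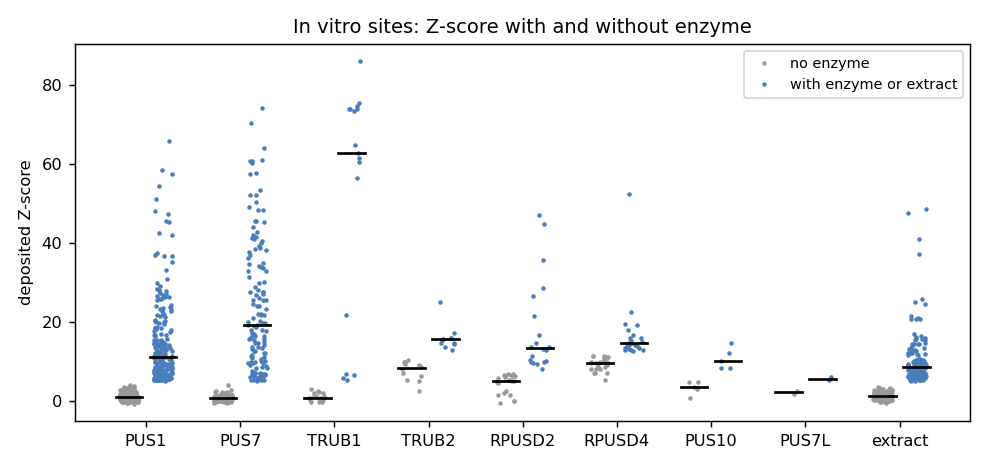
Deposited Z-score of each in vitro site (points) with no enzyme (grey) and with the enzyme or extract it is assigned to (blue); lines are medians. PUS7 sites had a median of 19.1 against 0.630 without enzyme, and RPUSD4 sites 14.5 against 9.58.

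PUS7 sites carried the PUS7 motif UNUAR: 133 of 139 (95.7%, 95% interval 90.8 to 98.4) matched, against 39 of 285 sites of other enzymes (13.7%; Fisher's exact test, adjusted p = 5.5e-65). TRUB1 sites matched the TRUB1 motif at 5 of 17 (29.4%) against 0 of 407, which allows up to 0.902% (adjusted p = 8.3e-08), and had a guanine at -2 in 94.1%. The sites in NOMO1, NOMO2 and NOMO3 had identical Z-scores and are not separate measurements; with such sites counted once, a choice made after the data were seen, 3 of 15 matched (adjusted p = 5.6e-05). PUS1 sites matched HRUAA at 24 of 226 (10.6%) against 16 of 198 (8.08%), a difference that did not pass (adjusted p = 0.408). The other sites included those of PUS7, of which 98.6% were followed by an adenine. At -1, PUS1 sites had an adenine in 42.9% and a guanine in 27.4%, against 26.9% and 16.9% at sites with no assignment. An adenine stood at +1 in 85.0% against 75.6%, but at +2 in 15.9% against 28.8%. These single bases were not tested. Among sites with no assignment, 474 of 4238 (11.2%) had the PUS7 motif.

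Peak values at single sites were deposited for 2 sets of in vitro libraries. In the first set, PUS7 gave the highest value at 7 of 10 sites. These included AFMID at position 76193224 (21.5, against -1.66 without enzyme), the p53 regulator gene MDM2 (17.4 against -0.807), RBM39 (17.0), NOMO3 (14.5) and the chromatin remodeller gene SMARCA1 (12.9). PUS1 gave the highest value at the tRNA synthetase gene IARS (5.88 against 0.826). In the second set of 70 sites, RPUSD2 was highest at 22, RPUSD4 at 20, TRUB2 at 14 and PUS10 at 11. The names of the RPUSD2, PUS10 and extract values carried another number prefix than those of RPUSD4, TRUB2 and both no-enzyme libraries. What the prefix stands for is not stated. The no-enzyme values may therefore not be matched to RPUSD2 and PUS10. RPUSD2 values were highest at a pair of SNHG14 sites (24.7 and 21.9) and at PPIA (17.8), with 1.29 or less in both libraries without enzyme. RPUSD4 values were highest at SAT1 (51, against 10.2 and 4.25 without enzyme), GMDS (22.1 against 1.47 and -6.65) and HNRNPC (21.4 against 7.82 and 5.38). PUS10 gave 51 at a GPC3 site (0 in both without enzyme), and TRUB2 at most 7.61, at HNRNPH1 (-3.33 and 0.715), where RPUSD4 gave 12.8. SAT1 and the GPC3 site had the same value of 51 and exactly 0 in other libraries. Reads per site are not given, so values that rest on few reads cannot be told apart. HNRNPC at 21678888 and C2orf88 had identical values in all 7 libraries, so they are not separate measurements.

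Between PUS1 knockout and wild-type HepG2 cells, 116 genes differed, 50 coded positive and 66 coded negative. The largest differences were negative: the pseudouridine 5'-phosphatase gene PUDP (ENSG00000130021) had a coded log2 fold change of -5.95 (SE 0.33) and the steroid sulfatase gene STS -4.77 (SE 0.35), both on chromosome X. The cell adhesion gene NRCAM (-4.69), the glycosyltransferase gene GALNT13 (-4.67), RNF217 (-3.85), CPNE8 (-3.38), the insulin receptor substrate gene IRS2 (-3.20) and the myosin light chain gene MYL9 (-2.84) followed. The highest were the Notch target HEY1 (2.66, SE 0.34), the metalloprotease gene MEP1A (2.31), the disulfide isomerase gene PDIA2 (2.24), the plasminogen gene PLG (2.18), the endoglin gene ENG (2.12), ACCS (1.96), the splicing regulator NOVA1 (1.85) and SLC37A2 (1.85). The non-coding RNA LINC02882 (2.13) and 3 genes without a standard symbol, of coded values -3.91, -3.37 and 2.16, also fell under the rule for named genes.

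These calls rested on the authors' DESeq2 adjusted p under 0.05 among 18939 genes, with 2 libraries per group. PUDP had an adjusted p of 4.5e-67 and HEY1 4.5e-12. All 116 had an absolute coded log2 fold change of at least 1, and 592 genes had an unadjusted p under 0.05. PUS1 itself was not called (0.13, SE 0.29, unadjusted p = 0.653). The table does not say which group is the numerator, so a negative value cannot be read as lower in the knockout.

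**Figure D3:**
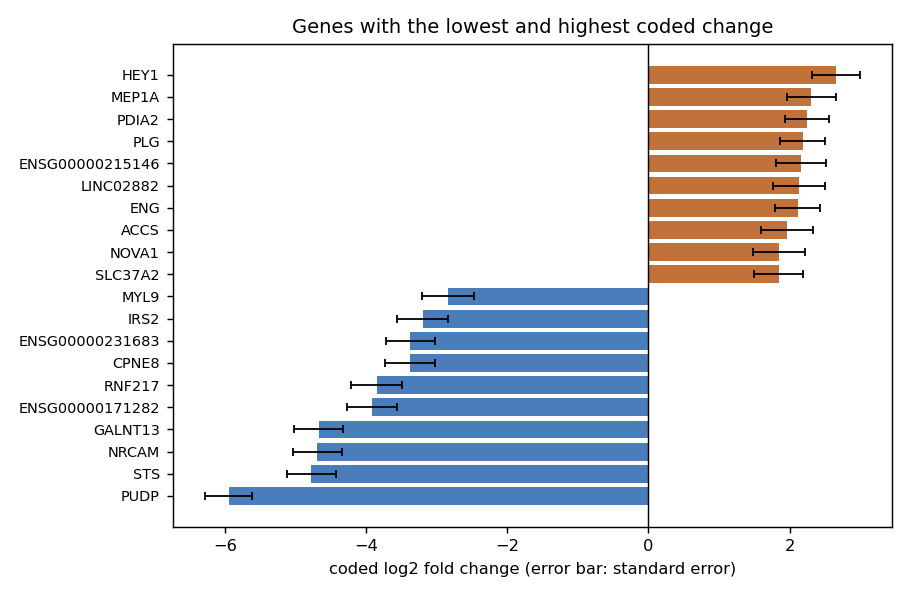
Coded log2 fold change (bars) and its standard error for the 10 lowest and 10 highest called genes with a mean of at least 100 normalized counts, PUS1 knockout and wild-type libraries, 2 per group. Values run from -5.95 (PUDP) to 2.66 (HEY1).

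Energy metabolism and protein folding lists moved in the positive direction. Of the 13 mitochondrially encoded mRNAs, 11 were positive (median 0.36, cameraPR adjusted p = 4.2e-04), with MT-ND6 and MT-CYB at 0.94 and MT-ND2 at 0.88, while MT-ATP8 was at -0.54. No member passed over all genes and 3 passed adjusted over the list alone. Nuclear-encoded oxidative phosphorylation genes were positive in 41 of 46 (median 0.19, adjusted p = 0.00187), with CYC1 at 0.41 and COX6A1 at 0.29. Endoplasmic reticulum chaperones were positive in 14 of 16 (median 0.25, adjusted p = 0.00410), among them MANF (0.49), SDF2L1 (0.48), CRELD2 (0.42) and DNAJB11 (0.39). In both, 0 members passed over all genes or adjusted over the list alone.

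Marker lists of bile duct and blood cells also moved. Bile duct and progenitor markers were negative in 5 of 7 (median -0.26, adjusted p = 0.0255), and the stem cell marker PROM1 passed on its own (-1.56, adjusted p = 0.00489). Blood cell markers were positive in 5 of 5 (median 0.19, adjusted p = 0.0198), led by the monocyte marker CD14, which passed adjusted over the list alone. By rank, both lists lost the call (adjusted p = 0.112 and 0.0679). The ATF4 list, with ATF3 at -0.71 and SLC7A11 at -0.59, was negative in 22 of 30 and missed the threshold (adjusted p = 0.103; 0.0334 by rank). The proliferation list was positive in 28 of 29, with CCNE2 at 0.35 and MCM6 at 0.25, and missed it too (adjusted p = 0.215; 0.0295 by rank). An estimated correlation could not be computed for any list.

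The other 15 lists had adjusted p between 0.215 and 0.953. They covered pseudouridine synthases (9 of 13 positive; PUS7 -0.34), H/ACA partners (NOP10 0.20), U2 snRNP factors (SNRPA1 0.30), SR proteins (CLK1 -0.43), hnRNP proteins (HNRNPUL2 -0.28), ribosomal proteins (45 of 59 negative; RPS10 -0.29), cholesterol synthesis (MVK 0.34), hepatocyte secreted proteins, hepatocyte metabolism (G6PC1 -0.80, ARG1 0.72), fetal liver markers (LIN28B 0.48, GPC3 -0.24), p53 targets (16 of 20 negative; BTG2 -0.49), interferon-stimulated genes (STAT2 0.62), hypoxia (ANKRD37 0.61), histones and mesenchymal markers (SNAI2 0.95). Members called in these were the fibrinogen gene FGB (-1.64, adjusted p = 4.2e-05) and the histone gene H2BC12 (1.78, adjusted p = 9.9e-05). The SR protein and secreted protein lists had a positive median and a negative mean.

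In the PUS1 comparison, 1523 skipped exons of 1198 genes were called, 785 with higher inclusion in the first group and 738 in the second. TMCC1 had the largest difference, with inclusion of 0.0515 ± 0.0728 (SD, n = 2) in the first group and 0.917 ± 0.118 in the second, at 129579783 to 129579855 of chromosome 3. Inclusion was also lower in the first group in the gasdermin gene GSDMB (-0.695), ZNF529 (-0.653), TMEM173, which encodes the innate immune adaptor STING (-0.619), AC159540.1 (-0.595), the cholesterol synthesis gene MVD (-0.591) and ADAM15 (-0.583). It was higher in ABCD4 (0.762) and RGL3 (0.699). A 62 nt exon of PUS1 itself, at 132414280 to 132414341 of chromosome 12, had inclusion of 0.859 in the first group and 1 in the second. RPUSD1 had called exons at -0.146 and -0.101.

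Other event types gave 395 alternative 3' splice sites, 297 retained introns, 238 alternative 5' splice sites and 113 mutually exclusive exons. The largest were a retained intron of RHBDF2 (0.827), PIK3C2B (0.698) and ESYT3 (-0.561), 3' splice sites of NAGPA (0.713), NUDT13 (-0.685) and SULT1C2 (0.561), 5' splice sites of DMKN (-0.600), C14orf159 (0.597) and ITFG2 (0.563), and mutually exclusive exons of TNFSF13 (0.504), SMPD4 (-0.490) and SLC25A36 (-0.487). Among synthase genes, RPUSD1 (0.282) and RPUSD4 (-0.110) had called 5' splice sites.

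The rMATS test called 9.73% of 15648 tested skipped exons, and the libraries of both groups did not overlap at 1101 of the 1523 calls. Among all tested exons 24.2% did not overlap, where chance gives 33.3% if no inclusion levels are equal. Equal levels counted as overlap, so the share can fall below that without a cause. The calls were selected for a large difference, so their higher share is no separate evidence. The limma test, which estimates spread between libraries, called 0 with an adjusted p under 0.05 and a difference of at least 0.1, and 838 exons had an unadjusted p under 0.05. In simulated data it recovered 26% of exons with a 4-fold change in odds, and 17.5% of its calls were false.

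With PUS7 knockdown, 77 exons of 74 genes were called, 40 higher in the first group and 37 in the second. The median inclusion difference over tested exons was 0.0207 between libraries of the same group and 0.0207 between groups. For PUS1 these were 0.0375 and 0.0385. The comparisons also differed in libraries per group and depth, so their numbers of calls do not rank the enzymes. The integrin gene ITGB4 had the largest difference, with inclusion of 0.790 ± 0.110 (SD, n = 3) against 0.463 ± 0.0811, at 73749846 to 73750055 of chromosome 17. The hyaluronidase gene HYAL2 (0.268), ZNF253 (0.255), PKD1P1 (0.255), KRBOX4 (0.240) and PAQR3 (0.239) were higher in the first group, and KIAA0196 (-0.281), C1orf109 (-0.254), ZNF280C (-0.246) and CAB39L (-0.232) lower. The libraries did not overlap at 59 of the 77, which were selected for a large difference. They did not overlap at 7.09% of all 19495 tested exons, where chance gives 10% if no inclusion levels are equal. limma called 0 with a difference of at least 0.1. It had 852 at an unadjusted p under 0.05 and 1 at an adjusted p under 0.05, in GPC3, with a difference of 0.025 (adjusted p = 6.0e-04). In simulated data it recovered 46% of exons with a 4-fold change, and 3.64% of its calls were false.

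After RPUSD4 knockdown, 542 exons of 486 genes were called, 296 higher in the first group and 246 in the second. The centriole gene CNTRL was at 0.224 ± 0.316 (SD, n = 2) in the first group and 1 in the second. TCP11L2 (-0.652), KANSL2 (-0.593), ERBB2IP (-0.560) and FAM86DP (-0.553) were also lower in the first group, and AKAP14 (0.755), SEC31B (0.575), SMTNL2 (0.559), MECR (0.549) and PORCN (0.548) higher. An exon of the synthase gene PUSL1 was at 0.923 ± 0.00636 and 0.459 ± 0.471 and had a limma p of 0.145; in the second group, 1 library had 2 inclusion and 10 skipping reads and the other 137 and 26. The libraries did not overlap at 471 of the 542, which were selected for a large difference. They did not overlap at 22.8% of all 18032 tested, where chance gives 33.3% if no inclusion levels are equal. limma called 0, with 491 at an unadjusted p under 0.05, and recovered 41% of simulated 4-fold changes, with 12.96% of the calls false. Significant events with small differences were missing from this table, so the share of all tested and the limma count cannot be set against chance.

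**Figure D4:**
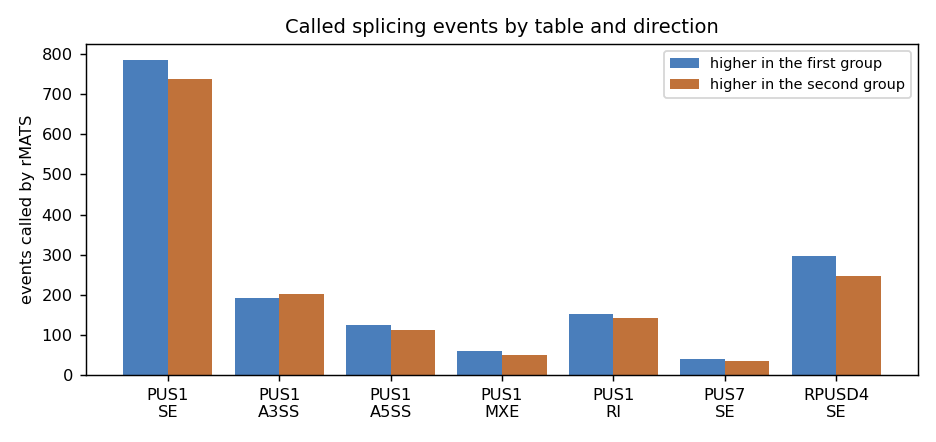
Events called by rMATS (FDR under 0.05, inclusion difference of at least 0.1) per table, by the group with higher inclusion; SE, skipped exon; A3SS and A5SS, alternative 3' and 5' splice sites; MXE, mutually exclusive exons; RI, retained intron. Skipped exons numbered 1523 for PUS1, 77 for PUS7 and 542 for RPUSD4.

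The comparisons shared more called exons than expected if every exon tested in both were equally likely to be called. PUS1 and RPUSD4 shared 88 against 31.8 (Fisher's exact test, adjusted p = 6.1e-19), PUS1 and PUS7 shared 15 against 5.17 (adjusted p = 1.7e-04), and PUS7 and RPUSD4 shared 5 against 1.78 (adjusted p = 0.0322). The coded sign was the same at 50 of 88, 8 of 15 and 1 of 5 of these. Over all exons tested in both, the Spearman correlation of the coded differences was 0.00452, 0.00893 and 0.00663, in the same order. Whether exons with few reads or variable inclusion are called more often in any comparison was not tested. The excess therefore does not show a shared response to the enzymes. With the FDR alone, the overlap of PUS7 with PUS1 lost its call (adjusted p = 0.0504). So did that with RPUSD4 (adjusted p = 0.120), but its table lacked the small differences that this setting adds, so that value tells nothing.

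Called skipped-exon events, which run from the upstream to the downstream exon, did not contain listed chromatin sites more often than other events. A site lay inside 43 of 1523 called PUS1 events (2.82%) and 654 of 14125 others (4.63%; Fisher's exact test, adjusted p = 0.00123), and inside 7 of 542 RPUSD4 events (1.29%) and 710 of 17490 others (4.06%; adjusted p = 9.6e-04). For PUS7 it was 3 of 77 (3.90%) and 735 of 19418 (3.79%; adjusted p = 0.768). Within genes that had a site, neither difference passed: the PUS1 shares were 36.8% and 36.4% (adjusted p = 1), and the RPUSD4 shares 24.1% (7 of 29) and 36.5% (adjusted p = 0.530). Sites assigned in vitro to the same enzyme lay in called events of ANKRD10 (0.245), PUM2 (0.203), ARHGAP5 (0.158) and TANK (-0.128) for PUS1 and NAP1L4 (0.125) for PUS7. Other called events with a site included, of the 43 for PUS1, those with large differences in the actin-binding gene GSN (-0.555), ENOSF1, PMM2, JMJD1C, HSD17B7P2, NFAT5, FMNL2 and PRPF39. They were in TFPI (0.147) and GPBP1L1 (-0.189, with libraries that overlapped between groups) for PUS7, and in MATR3 (-0.214), FOXN3, ATXN2L, C17orf76-AS1, SREK1, CCNL1 and GPBP1L1 (-0.182) for RPUSD4.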

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

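The settings with a block by position, non-overlapping libraries, a no-enzyme limit, identical Z-scores counted once, sites of the same enzyme and another FDR were chosen after the results were seen. The number of expression calls ranged from 82 to 116 over its alternatives, and 3 of the 5 lists called passed in all of them. With limma, each alternative, each left-out library (0 to 0 events in each comparison, where a lone sample is assumed to vary like the others) and the replicate block (0 events) called 0 exons. An inclusion difference of at least 0.05 gave 2522 skipped exons, 668 and 400 alternative 3' and 5' splice sites and 500 retained introns for PUS1, and 156 skipped exons for PUS7; for RPUSD4 it tells nothing, since significant events with small differences were missing. At least 0.2 gave 605, 147, 99, 111 retained introns and 46 mutually exclusive exons for PUS1, 16 for PUS7 and 198 for RPUSD4. FDR under 0.01 gave 63 mutually exclusive exons and 195 retained introns for PUS1, 22 exons for PUS7 and 263 for RPUSD4. With no read minimum PUS7 had 173. These follow from the thresholds themselves. With the FDR recomputed over the listed events RPUSD4 had 419. With the FDR alone, 50 exons were shared by PUS1 and PUS7 and 9 by PUS7 and RPUSD4, both no longer past the threshold (adjusted p = 0.0504 and 0.120); the cause was not tested, and the second tells nothing, for the same lack in the RPUSD4 table.

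The odds ratio for a site inside a called event turned from 0.598 to 1.01 for PUS1 and weakened to 0.553 for RPUSD4 within genes with a site, where neither passed the threshold (adjusted p = 1 and 0.530). It turned from 1.03 to 0.717 for PUS7 within 500 nt. With sites of the same enzyme it was 0.462 for PUS1 and 0 for RPUSD4, both no longer past the threshold; few sites remained. For PUS7 it was 3.80 with sites of the same enzyme (1 of 77 events against 67 of 19418) and 2.74 within genes with a site, neither past the threshold (adjusted p = 0.354 and 0.530). The intronic share of chromatin sites was 42.0% in the upper part of the peak values, 30.4% at 8 or more pairs and 12.9% at 10 or more; the cause was not tested. The upper part of the Z-scores gave, by construction, 113 PUS1, 70 PUS7, 9 TRUB1, 6 TRUB2, 10 RPUSD2, 12 RPUSD4, 3 PUS10, 1 PUS7L and 72 extract sites. A no-enzyme Z-score under 5 left 2 TRUB2, 11 RPUSD2 and 0 RPUSD4 sites. The lists of SR proteins (adjusted p = 0.982), secreted proteins (0.558) and histones (0.982) turned direction under 1 alternative each without a call. By rank, the ATF4 (0.0334) and proliferation (0.0295) lists gained a call and the bile duct (0.112) and blood cell (0.0679) lists lost theirs. Depth per library is unknown outside the splicing tables.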

Other observations

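The tests of base composition, of low support, of known motifs, of the placement of the lowest genes, of pooled reads, of simulated power and of other splits were chosen after related results were seen. In chromatin RNA, peaks in at least 10 of 11 pairs were found at 5 of 17 TRUB1 sites, 2 of 20 RPUSD2 sites, 4 of 143 extract sites, 8 of 226 PUS1 sites and 1 of 139 PUS7 sites, and at 0 sites of the other enzymes; the differences were not tested. In mitochondrial RNA 7 of 47 sites reached 10 pairs, and in the ribosomal RNA precursor 24 of 81.

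An adenine followed most listed chromatin sites, and mainly those seen in the fewest library pairs. Local base composition does not account for this, since the share was 3.84 times that of other uridines nearby. Outside sites with the PUS7 or PUS1 motif or an in vitro assignment, it was 3.53 times. This does not exclude a preference of PUS1. The PUS1 motif matched 10.6% of the PUS1 in vitro sites, whereas an adenine followed 85.0% of them. Reverse transcription or cleavage ends at UA steps in low-support sites remain a candidate explanation, since the share was 26.0% at sites in 10 or 11 pairs. Within introns it was 87.2% at 7 pairs and 54.5% at 10 or 11 (Fisher's exact p = 2.0e-04). At in vitro sites it was 98.6% for PUS7, 96.5% for the extract, 85.0% for PUS1, 70% for RPUSD2 and 58.8% for TRUB1. It was 100% for RPUSD4, TRUB2 and PUS10 and 0% for the 2 PUS7L sites. Sites with no assignment had 75.6%. A preference of synthases, tested here or not, stays open.

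PUDP and STS, the lowest genes, overlap at their ends on chromosome X. Loss of a chromosome segment in 1 line cannot be told apart from regulation, since 0 other genes inside the segment had a mean of at least 10. PNPLA4, the next such gene, was at -0.14 (SE 0.30), outside it. Chance placement is not decided: 2 random tested genes lay within 1 Mb of each other in 0.155% of draws, but 10 random genes, as many as the lowest genes named, held such a pair in 6.37%, and the pair was noticed after its position was seen.

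rMATS called many skipped exons where limma called 0 and had, at an unadjusted p under 0.05, 838 exons for PUS1 (5.36% of those tested, where chance gives 5%; 769 and 1195 in the other splits of the libraries), 852 for PUS7 (4.37%; 667 to 1847) and 491 for RPUSD4 (2.72%). The RPUSD4 table lacked significant events with small differences, so its counts cannot be set against chance or other splits. A test on reads pooled within groups, blind to the spread between libraries, made 1316 calls for PUS1. The other splits gave 1165 and 1660. For PUS7 it made 81, and 26 to 383 in the others. The real split was therefore not the one with the most calls in either comparison. The highest PUS1 counts, 1195 with limma and 1660 with pooled reads, came from the split by position in the list. A batch shared by libraries at the same position is therefore possible, but replicate numbers are not given. The most in another split was 1.26 times the real count or more in both, so spread between libraries may account for many rMATS calls. In simulated data of this size limma recovered at most 46% of 4-fold changes and at most 7% of 2-fold changes. The simulation gave all exons the same SD and changed only exons of intermediate inclusion, so recovery in the data may be lower. Whether too few libraries account for the 0 calls is therefore not decided. Changes in splicing due to the enzymes themselves stay open.

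For PUS7 all 10 splits of the 6 libraries into equal groups gave as many limma calls (real 0, highest other 0), and 10 splits are too few for a share under 0.05. For RPUSD4 a split by position gave 2, in a table with that limit.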
